A study of Mus musculus with 2 samples.

How the data were processed

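Parietal cells of the stomach were obtained by cell sorting from HFD-fed and control C57BL/6 mice, 1 library per diet. Per the labels' protocols, total RNA was prepared with an AllPrep kit and treated with DNase I, ribosomal RNA was removed with RiboMinus, and libraries were made with the Ion Total RNA-Seq Kit v2; no poly(A) selection step is named. The number of mice behind each library and the markers used for sorting are not given in the sources used here. The submitters' processing notes name bedtools 2.25.0 and the genome build mm10; the aligner, the counting rule and the annotation release are not given in the sources used here.

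Each deposited table holds 1 value for each of 38087 Ensembl gene identifiers in a column headed RPKM. The values were found to be log2 of RPKM as deposited, with no pseudocount, and genes at or below 1 RPKM listed as 0. This reading rests on 3 properties of the values: the largest was 18.22, no listed gene lay between 0 and 1 RPKM (smallest 1.0006 and 1.0013), and 2 to the power of the value, times gene length, fell on whole multiples of a fixed step for single-exon genes. The step gave 25.49 M reads for the HFD library and 9.84 M for the control library, a ratio of 2.59. At 12 steps or fewer, 88 of 178 values (49.4%) and 243 of 702 (34.6%) were whole within 0.005 of a step, against 1% by chance. The files used here hold no counts, so no count model was run. A gene listed at 0 can hold reads below the floor, and no fold is printed against it, though counts of genes over 2-fold include such genes.

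Gene symbols, biotypes, positions and exon lengths came from GENCODE release M21 on GRCm38, the assembly also called mm10; 36308 identifiers matched and 1779 did not. None of the 37 mitochondrially encoded genes of the annotation was among the identifiers, so the list of mitochondrially encoded subunits was not analysed here. A gene counted as measured when listed above 0 in either library. The ratio was log2(RPKM in HFD + 1) minus log2(RPKM in control + 1), with genes listed at 0 entered as 0 RPKM. Values were used as deposited, without rescaling. The pseudocount of 1 understates the ratio of low genes listed in both libraries. A gene listed in 1 library only passes 2-fold on this scale by construction, since each listed value lies above 1 RPKM. Ratios of genes listed in both libraries are of RPKM without a pseudocount, with an exact conditional binomial 95% interval from reads estimated as RPKM times exon length times depth. These intervals are approximate, since lengths come from another annotation release, and reads without molecular identifiers are not independent molecules.

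Design, alternatives and 45 gene lists with 900 entries were fixed before the data were examined. For each of the 44 lists with a measured member the median ratio was placed among 10000 random lists of the same size, matched on 20 bins of mean expression, as planned. The random genes were drawn from all measured genes, small RNA genes included. A first version had also matched on class (protein-coding or not), a choice made after the data were seen and not part of the plan; it put 3 more lists outside the range and is given only as an alternative. A list was taken to stand apart below percentile 2.5 or above 97.5; about 2.2 of 44 lists would do so by chance if genes were independent. The percentile describes these libraries and does not test diet. With 1 library per group no p-value across genes, replicate check, outlier check or permutation of labels was possible. The planned test for counts did not apply, and the planned form for normalized values was used.

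Genes were named by a fixed rule: the 12 highest and 12 lowest ratios among genes of at least 5 RPKM in a library, leaving out predicted genes, clones, small RNAs and pseudogenes; of each list described, up to 4 members of the highest mean level and the highest and lowest ratio with at least 50 estimated reads; each parietal marker; and the 10 most abundant genes of each library. A few further genes (Hadhb, Irf7, Isg15, Usp18, Ifit1, Psmb8 and Rpl13) were chosen after their values were seen. Where several identifiers shared a symbol, the one with the highest total was used.

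The calculations were tested on simulated data for the comparison of the HFD with the control library: reads were drawn from a Poisson distribution around the mean RPKM of the real genes at both depths, with 200 coding genes changed. Depth was recovered to a ratio of 1.00 in each library. In the simulation 100% of the checked values were whole, against 49.4% in the real HFD library and 34.6% in the real control library. Reads were drawn and depth was recovered with the same gene lengths. The simulation therefore tests neither the depth nor the intervals against error in those lengths or in the counting rule. Of 100 genes changed 4-fold, all passed 2-fold in the true direction, with a median recovered log2 ratio of 1.79; of 100 changed 2-fold, 17.0% passed, with a median of 0.90. The true ratio lay in the interval for 95.8% of 10601 unchanged coding genes, 2.22% of unchanged coding genes passed 2-fold by counting alone, and 2 of 100 unchanged lists of 20 genes lay outside the central 95%.

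Alternatives planned were 4 scalings of the HFD values, a pseudocount of 0.1 RPKM, a minimum of 5 RPKM or none, thresholds of 1.5-fold and 4-fold, sums over identifiers of a symbol, and 5 bins for the random lists. Alternatives added after seeing the data entered genes listed at 0 as 1 RPKM, used only genes listed in both libraries, required the whole interval beyond 2-fold, used protein-coding genes only, drew random lists from genes of the same class, took out the trend on GC content and transcript length, or left out members that hold a small RNA. The trend was taken out by subtracting medians over 20 bins of GC content and 20 of length of the longest transcript, in 5 rounds, over 11976 coding genes. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.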

Results

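RNA was measured in parietal cells, the acid-secreting cells of the gastric glands, sorted from the stomachs of C57BL/6 mice that had been fed a high fat diet (HFD) or a control diet. Each diet was represented by 1 sequencing library, so the comparison had no replicates and no difference between the diets could be tested. All differences below are between these 2 libraries. The deposited values covered 38087 Ensembl genes per library, of which 13431 lay above the floor of 1 RPKM (reads per kilobase of gene, per library depth in M reads) in the HFD library and 15045 in the control library. The depth estimated from the spacing of the values was 25.49 M reads for the HFD library and 9.84 M for the control library. A gene of 2 kb at 1 RPKM therefore rested on about 51 reads in the HFD library and 19.7 in the control library. Intervals given with ratios are approximate 95% intervals from the estimated reads; they cover counting error only and say nothing about variation between mice.

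The comparison of the libraries asked how the transcripts of the sorted cells differed between the HFD and the control library. Interferon-response genes were higher in the HFD library, with a median of 0.80 on the log2(RPKM + 1) scale and 15 of 20 genes higher, among them Oas1a at 5.07 times the control (interval 4.09 to 6.30). Cell cycle genes were lower in the HFD library, with a median of -1.28 and 23 of 24 genes lower, as were digestive enzymes typical of pancreatic acinar cells, with 12 of 12 lower. Of these, 9 were listed at 0 there, so their median of -5.09 depends on how a 0 is entered (-4.09 as 1 RPKM, -8.37 with a pseudocount of 0.1 RPKM, -2.86 over the 3 listed in both). Markers of gastric endocrine cells, fibroblasts and smooth muscle were lower as well, with medians of -2.04, -1.62 and -1.70. Under other minimums and ways of entering a 0 these were -1.33 to -2.52, -1.11 to -1.81 and -1.33 to -2.70. Genes of the parietal cell itself (median 0.44, 14 of 18 higher) and of fatty acid oxidation (median 0.34, 20 of 23 higher) were mostly higher. Both lay within the range of random gene lists of similar expression, which include small RNA genes. Against random lists of the same class, an alternative chosen after the data were seen, they lay at percentiles 99.62 and 98.91. Their medians were below 0 under 1 of 4 other scalings.

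The proton pump of the parietal cell was abundant in both libraries, but some markers of other gastric cells stood higher. Pgc of chief cells stood at 45624 RPKM in the HFD library and 102292 in the control library. Gkn1 of pit cells stood at 21736 and 5021 RPKM, and Tff2 of neck cells at 7355 and 8350 RPKM. Differences between the libraries can therefore not be assigned to parietal cells alone. Atp4a (ENSMUSG00000005553, chromosome 7, 30712209 to 30725534, mm10), the catalytic subunit, stood at 4997 RPKM in the HFD library and 4324 in the control library, a ratio of 1.16 (1.15 to 1.16). Atp4b (ENSMUSG00000031449, chromosome 8, 13386205 to 13396825), the beta subunit, stood at 5639 and 4375 RPKM, a ratio of 1.29. Larger ratios were seen for the potassium channel gene Kcnj16 at 2.16 (165 against 76.2 RPKM), the histamine receptor gene Hrh2 at 2.39 (39.5 against 16.5 RPKM), the chloride and bicarbonate transporter gene Slc26a7 at 2.59 (14.2 against 5.48 RPKM) and the water channel gene Aqp4 at 2.96 (11.3 against 3.82 RPKM). Car2, the carbonic anhydrase that supplies protons and bicarbonate, was 1.81 times as high (1561 against 861 RPKM), Slc26a9 1.89 times, Kcnj15 1.65 times, and Esrrg, a nuclear receptor of mitochondrial and parietal genes, 1.52 times. Kcnq1 and Slc4a2, which encode the apical potassium channel and the basolateral anion exchanger, had ratios of 1.39 and 1.34, Slc9a4 had 1.16 and Clic6 1.02. Kcne2 (ratio 0.907) and Ezr (0.916) were slightly lower. Of the secretagogue receptors besides Hrh2, the muscarinic receptor gene Chrm3 stood at 2.90 against 6.24 RPKM and the gastrin receptor gene Cckbr was listed at 0 in the HFD library against 3.67 RPKM in the control library. The parietal median lay at percentile 93.49 of 10000 random lists matched on expression, inside their central 95%; it lay outside, at 99.62, only where the random genes were also matched on being protein-coding, with 5 expression bins (98.3) or with no minimum (97.81). In the same comparison 25 genes of ion transport and membrane traffic in acid secretion had a median near 0 (-0.06, percentile 41.21), with Rab11a highest at 2.29 times the control. With the HFD values rescaled to the total without the 20 most abundant genes, the median of all measured genes moved from -0.13 to -0.63, that of the parietal markers to -0.16, and 7 of the 18 were then higher.

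Interferon-response genes stood apart from matched random lists in the same direction (percentile 100). Their median of 0.80 stayed above 0 under each of 4 other scalings, but the largest shift of the HFD values, -0.61 on the log2 scale, was smaller than this median. The median was 0.27 scaled to the total without the 20 most abundant genes and 0.25 with no minimum. The antiviral gene Oas1a stood at 25.3 against 4.99 RPKM. Isg15, Usp18 and Irf7, all induced by type I interferon, had ratios of 5.10, 3.54 and 3.17, with levels under 11 RPKM in both libraries. Ifit1 and Psmb8 were listed at 0 in the control library. Class I antigen genes went both ways. H2-K1 was 2.12 times lower in the HFD library (50.7 against 108 RPKM) and H2-D1 1.35 times lower, whereas B2m had a ratio of 1.18. Ifi27 stood at 61.5 against 33.6 RPKM. Of 21 leukocyte markers only 8 were listed in either library, 7 of them higher in the HFD library and none above 15 RPKM, with a median of 1.35 (percentile 99.96). Over all 21, with no minimum, the median was 0.00 and the list no longer stood apart. The higher ones included the class II antigen genes H2-Aa (11.2 against 1.67 RPKM), H2-Eb1 (6.01 against 1.40 RPKM) and Cd74 (14.8 against 5.11 RPKM). Interferon genes and these markers were thus both higher, but 1 comparison cannot show that they change together. Among 15 measured inflammation genes the median was -0.09 (percentile 69.7), with 7 higher and 8 lower. It was 0.43 at a minimum of 5 RPKM and 0.20 over genes listed in both libraries, so no direction is given.

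The fatty acid oxidation list lay at percentile 95.57, inside the central 95% of random lists, and at 98.91 against random lists of the same class. Its median was -0.25 with the total without the 20 most abundant genes as the scale. Acadvl, which starts the oxidation of very long chains, was 2.33 times as high in the HFD library (156 against 67.2 RPKM; interval 2.21 to 2.45). Hadha, the alpha subunit of the trifunctional protein, was 2.15 times as high (141 against 65.6 RPKM) and its partner Hadhb 2.63 times. Acaa2 and Eci1 had ratios of 1.19 and 1.08, and the electron transfer flavoprotein gene Etfb was the lowest, 2.80 times lower in the HFD library. PPAR target genes were mixed (9 of 14 higher, median 0.20, percentile 86.65, below 0 under 2 of the other scalings): the fatty acid transporter gene Cd36 had a ratio of 2.37 and Acot2 2.74, whereas Pdk4 was listed at 0 in the HFD library against 3.08 RPKM. Nuclear-encoded subunits of the respiratory chain did not stand apart, with medians of 0.02 over 36 complex I genes, 0.02 over 26 genes of complexes II, III and IV, and 0.08 over 16 ATP synthase genes; the sign of these small medians changed with the scaling. Cholesterol synthesis genes were lower (17 of 23, median -0.41, percentile 1.58, but 2.68 and no longer apart at a minimum of 5 RPKM), including Srebf2 at 35.5 against 74.2 RPKM and Mvk at 3.14 against 16.4 RPKM.

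Proliferation genes and replication-dependent histone genes were lower together. Mcm6 and Mcm3, subunits of the replicative helicase, stood at 18.6 against 41.4 RPKM and 13.1 against 36.2 RPKM, and Plk1 at 16.4 against 37.6 RPKM. Ccnb2, a mitotic cyclin, was 9.10 times lower in the HFD library (2.26 against 20.6 RPKM; interval 7.18 to 11.7), and Bub1 was the single member that was higher, with a ratio of 1.06. All 21 measured histone genes were lower, with a median of -1.37, among them Hist1h1e (205 against 510 RPKM), Hist1h4d (232 against 462 RPKM) and Hist1h2ae (4.01 against 91.4 RPKM). Near-identical histone copies can share reads, so values of single histone genes are uncertain. Both lists lay at percentile 0.00. The 4 other scalings shift the HFD values by -0.61 to 0.02 on the log2 scale, too little to change the sign of these medians.

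Markers of other cell types differed in both directions. Pit cell markers, genes of the surface mucous cells, were higher (8 of 10, median 0.56) but inside the range of random lists (percentile 87.5). Against random lists of the same class they lay at percentile 99.27. They were led by Gkn1 at 21736 against 5021 RPKM, a ratio of 4.33 (4.29 to 4.37), and Gkn2 at 8091 against 3406 RPKM. Tff1 (ratio 0.986) and Psca (1.02) were close to equal. Rescaled to the total without the 20 most abundant genes, the pit cell median was -0.023. Chief cell genes were lower in 4 of 5 cases (median -0.64, percentile 4.02): the pepsinogen gene Pgc, among the most abundant genes of both libraries, stood at 45624 against 102292 RPKM, and Pga5 was 3.95 times lower. The hormone genes Ghrl (ghrelin, 707 against 5913 RPKM, 8.36 times lower), Sst (somatostatin, 150 against 1046 RPKM) and Chga (chromogranin A, 233 against 1204 RPKM) were lower, while Gast (gastrin) had a ratio of 1.16. In smooth muscle, Tagln was 15.9 times lower (interval 13.1 to 19.3) and Acta2 7.53 times lower; in fibroblasts, Col3a1 stood at 24.2 against 50.9 RPKM and Col6a1 at 4.48 against 24.8 RPKM. Globin and other erythroid genes were lower in 5 of 5 cases (median -1.26, percentile 0.10), but no longer stood apart without the trend on GC content and length (-0.96, percentile 3.37). Neck cell (median -0.15, and 0.08 without the trend on GC content and length), endothelial (-0.71), adipocyte (-1.33 over 3 genes, of which Cidec was listed at 0 in the HFD library, and -0.33 over the other 2) and intestinal epithelium markers (0.32, and -0.18 scaled to the total without the 20 most abundant genes) lay inside the central 95% of random lists, as did 13 markers of spasmolytic polypeptide-expressing metaplasia (-0.21), a mucous cell state of the injured stomach.

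**Figure D1:**
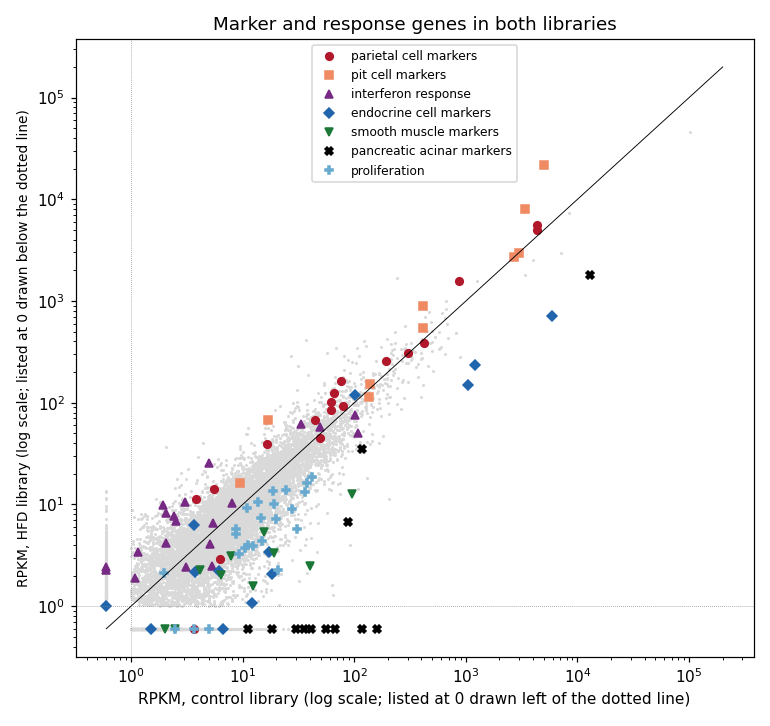
RPKM of protein-coding genes (grey) and of the members of 7 gene lists (coloured symbols) in the control library (horizontal, log scale) and the HFD library (vertical, log scale), 1 library each; the diagonal marks equal values and genes listed at 0 are drawn outside the dotted lines at 1 RPKM. Pancreatic acinar, endocrine, smooth muscle and proliferation genes lie mostly below the diagonal, and 9 of the 12 pancreatic genes were listed at 0 in the HFD library.

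Across all 16037 genes listed in either library, 2000 were over 2-fold higher and 3833 over 2-fold lower in the HFD library on the log2(RPKM + 1) scale. Of these, 992 and 2606 were listed at 0 in the other library. Such a gene passes 2-fold on this scale by construction, even at a value just above the floor of 1 RPKM. Rescaled to the total without the 20 most abundant genes, the split was 1102 higher and 5645 lower. Among 12439 genes listed in both, 1319 were over 2-fold higher and 1633 over 2-fold lower by the ratio without a pseudocount. The whole counting interval lay beyond 2-fold for 772 that were higher and 1054 that were lower. Protein-coding genes listed in both had a median log2 ratio of -0.04 with quartiles of -0.57 and 0.43. Among protein-coding genes, 8.0% were over 2-fold higher and 20.1% over 2-fold lower. Of these, 488 of 961 and 1491 of 2404 were listed at 0 in the other library and passed by construction.

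The 12 genes with the largest excess in the HFD library, among annotated genes of at least 5 RPKM, were led by the immunoglobulin variable segment Ighv1-9 (chromosome 12, 114583569 to 114584002; 40.2 RPKM, listed at 0 in the control library). Igkv1-88, a light chain segment, stood at 24.6 RPKM, and the antisense transcript Cdrt4os1 at 25.1 RPKM, both listed at 0 in the control library. Chil4 (13.5 RPKM), a chitinase-like protein gene, and Ifnk (13.3 RPKM), which encodes a type I interferon, were likewise listed at 0 there, as were Spata18 (11.6 RPKM), Cox4i2 (11.4 RPKM), Rapgef4os2 (9.85 RPKM) and Prr19 (9.68 RPKM). The remaining 3 were measured in both libraries: the antisense gene Rab26os (625 against 42.8 RPKM, ratio 14.6), Fcgbp (37.0 against 2.07 RPKM, ratio 17.9; interval 15.6 to 20.6), a mucus protein gene, and Lypd8 (415 against 36.9 RPKM, ratio 11.2). Reads of antisense genes and their partners, and of related immunoglobulin segments, may be mixed because the counting rule is not given in the sources used here. At least as large an excess was found for 123 predicted, small RNA or pseudogene entries that are not named.

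The 12 genes with the largest deficit were all listed at 0 in the HFD library, and 9 of them encode pancreatic digestive enzymes. Ctrb1 (chymotrypsinogen; ENSMUSG00000031957, chromosome 8, 111686519 to 111691010) stood at 159 RPKM in the control library, Cela2a (elastase) at 117, Pnlip (pancreatic lipase) at 66.9, the amylase genes Amy2a2 and Amy2a5 at 65.9 and 55.3, Prss2 (trypsinogen) at 41.2, Cpa1 (carboxypeptidase) at 35.8, Ctrl at 30.9 and Cela3b at 30.3 RPKM. The other members were the histone genes Hist1h2ai (44.8 RPKM), Hist1h2ag (38.2 RPKM) and Hist1h2ah (37.0 RPKM). Of the pancreatic list, 3 genes were listed in both libraries: Clps, colipase, at 1790 against 12989 RPKM, Try4 at 34.9 against 116 RPKM and Cel at 6.66 against 87.5 RPKM. Amylase and trypsinogen copies are close paralogs, so their single values are uncertain. Another 23 predicted, small RNA or pseudogene entries had a deficit at least as large.

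Small nuclear and nucleolar RNAs made up a larger part of the HFD library. Of 219 snoRNA genes listed in both libraries, 198 were higher in the HFD library, with a median log2 ratio of 1.89. More snoRNA genes were listed in the control library (299) than in the HFD library (260). A single read equalled an RPKM times length in bases of 101.674 in the control library and 39.224 in the HFD library. Short genes thus passed the floor of 1 RPKM on fewer reads in the control library, so these numbers give no direction. The share of all RPKM held by snoRNA genes was 21.7% against 7.10%. RPKM weights short genes, and of the estimated reads they held 2.74% against 0.69%. The 59 snRNA genes listed in both libraries had a median of 2.80, and the 403 long noncoding RNA genes listed in both one of 0.34. In all, 128 snRNA genes were listed in the HFD library and 100 in the control library. For long noncoding RNA genes the numbers were 561 and 726, so the median of 0.34 leaves out many listed in the control library only. Ribosomal 5.8S RNA, n-R5-8s1, was the most abundant entry of both libraries at 304350 and 285593 RPKM. The other entries among the 10 most abundant of a library were Pgc, Gkn1 and Clps, the snoRNAs Snord55 (39525 against 10460 RPKM) and Snord32a (21331 against 5495 RPKM), the predicted microRNA genes Gm24187, Gm23935, Gm24270 and Gm25911, with ratios of 0.431 to 0.492, and 3 identifiers without a gene model. Ribosomal protein genes were lower in 35 of 47 cases (median -0.55, percentile 0.01; -0.28 without the trend on GC content and length), with Rpl5 among the exceptions at a ratio of 7.47. Processed pseudogenes can take reads of ribosomal protein genes, so their levels are uncertain.

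**Figure D2:**
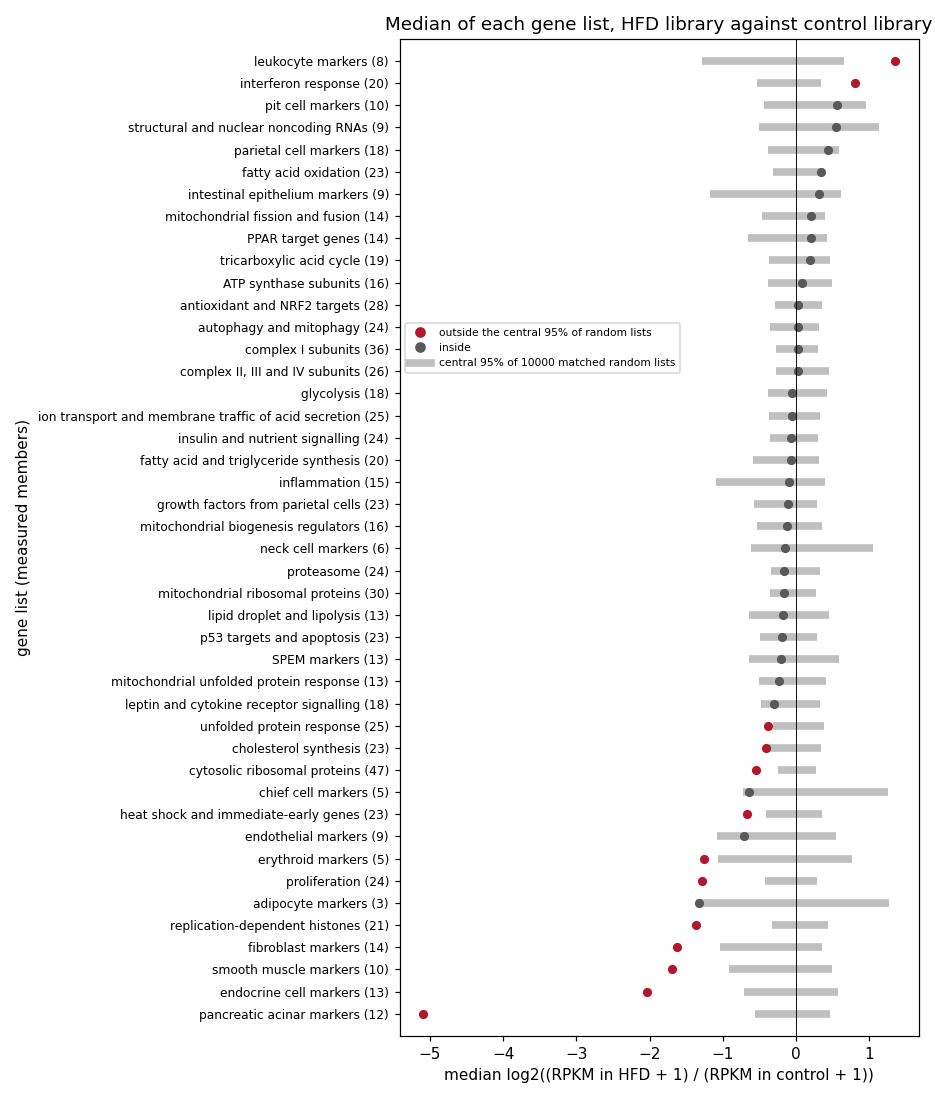
Median log2((RPKM in HFD + 1) / (RPKM in control + 1)) of 44 gene lists with their measured members in parentheses (dots; red outside the central 95% of 10000 random lists matched on expression, grey inside), with that central range as a grey bar; SPEM is spasmolytic polypeptide-expressing metaplasia. Above the range were 2 lists and below it 11; with the total without the 20 most abundant genes as the scale, the medians of parietal (-0.16), pit cell (-0.023) and fatty acid oxidation genes (-0.25) were below 0.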

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

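Of the 13 lists that stood apart, 10 did so with the same sign under all 14 alternatives, and 604 of 616 list values kept their call. Several alternatives could hardly change a call. The scalings also rescale the random lists, so percentiles barely moved (parietal markers 91.93 to 93.57, against 93.49). Summing identifiers touched 1 listed symbol, and leaving out small RNA hosts removed no member of many lists. Both counts therefore overstate how far the calls were tested. The alternatives chosen after seeing the data were those on genes listed at 0, genes in both libraries, counting intervals, coding genes, random lists of the same class, GC content and length, and small RNA hosts. Scaling to the total without the 20 most abundant genes put the medians of parietal markers (-0.16), pit cell markers (-0.023) and fatty acid oxidation (-0.25) below 0, by construction since it lowers each HFD value. Against random lists of the same class, parietal markers (0.44), pit cell markers (0.56) and fatty acid oxidation (0.34) stood apart; parietal markers also did with no minimum (0.44) and with 5 bins (0.44), and fatty acid oxidation at a minimum of 5 RPKM (0.34). With no minimum the leukocyte median was 0.00, since most members are listed at 0 in both libraries, and endothelial markers (-0.66) stood apart. At a minimum of 5 RPKM cholesterol synthesis (-0.40) no longer did. Without the GC and length trend erythroid markers (-0.96) no longer did, and PPAR targets (0.44) and mitochondrial ribosomal proteins (-0.36) did; the cause was not tested.

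Genes over 2-fold higher and lower numbered 2000 and 3833 as reported, 1102 and 5645 under that same scaling, 1092 and 1393 at a minimum of 5 RPKM, 1305 and 1878 with genes listed at 0 entered as 1 RPKM, 1319 and 1633 among genes in both libraries, 772 and 1054 with the whole interval beyond 2-fold, and 961 and 2404 among coding genes; apart from the scaling, each of these tests fewer genes or asks more of a gene. At 1.5-fold they numbered 3298 and 5265, at 4-fold 568 and 804. Scaling to the total gave 1572 and 4350, upper quartile 1692 and 4152, and median-of-ratios 2035 and 3776; the median of all genes moved to -0.32, -0.26 and -0.11. The 24 genes named by size kept their sign under each alternative run. Most of them are listed at 0 in 1 library and the rest have ratios of 11.2 or more, so these alternatives could not change a sign. Of 294 values of named genes, 80 moved by more than an allowance. For genes listed in both libraries this was the distance from the middle to the end of the counting interval on the log2 scale. Genes listed in 1 library only have no such interval and were allowed 1 log2 unit, so the 80 does not measure counting error for them. Planned minimums of 50 and 1 reads and a pseudocount of 5 reads need counts and were not run; 2-fold on the ratio itself is the reported count. No paired analysis was possible because each diet has 1 library. At the control depth, a gene of 2 kb listed at 1 RPKM rests on 19.7 reads.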

Other observations

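Stress and signalling genes not described above were mostly close to the rest of the transcriptome. Unfolded protein response genes were lower in the HFD library (17 of 25, median -0.39, percentile 1.19), among them the chaperone genes Hsp90b1 (1.67 times lower), Calr at 243 against 373 RPKM and Sdf2l1 at 2.58 against 42.2 RPKM, whereas Chac1 was 7.06 times as high (7.45 against 1.06 RPKM). Heat shock and immediate-early genes, which respond to cell dissociation, were lower in 16 of 23 cases (median -0.67, percentile 0.09), and the median was -0.43 without the trend on GC content and length. Fosb was 4.56 times lower and Fos stood at 62.8 against 74.8 RPKM, whereas Hspa8 (1699 against 240 RPKM), Klf4 (114 against 79.1 RPKM) and Btg2 (62.3 against 41.6 RPKM) were higher. Leptin and cytokine receptor signalling genes had a median of -0.30 (percentile 11.68), which rested on members near the floor (0.01 at a minimum of 5 RPKM, percentile 60.06), with Socs3 listed at 0 in the HFD library against 5.76 RPKM in the control library.

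Growth factors of the parietal cell went both ways (10 higher, 13 lower, median -0.11, but 0.27 at a minimum of 5 RPKM and 0.04 over genes listed in both libraries): Vegfb stood at 93.0 against 30.6 RPKM and Shh, a parietal morphogen, at 7.01 against 2.30 RPKM, while Egf stood at 4.83 against 18.5 RPKM. Of the antioxidant genes, Nqo1 (194 against 92.2 RPKM), Cat (136 against 62.9 RPKM) and Gsta3 (106 against 43.8 RPKM) were higher and Sod1 (20.4 against 73.2 RPKM) and Gpx3 (4.08 against 16.5 RPKM) lower, with 14 of 28 in each direction. Of the regulators of mitochondrial biogenesis (median -0.13), Ppargc1a had a ratio of 2.70 and Tfam one of 0.382. Shh, Egf, Cat, Gsta3 and Gpx3 were picked here after their values were seen. The remaining lists lay between percentiles 10 and 90.

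The tests on host genes, on the share of other cell types and on chief cells were chosen only after the results were seen, as was counting a list that lay inside the random range before the GC correction as undecided. The host test replaced a first version, whose result was seen and is given too, and its rule was then made stricter after the second result. The test on other cell types replaced earlier ones on the percentiles of pit cell and then leukocyte markers (99.96 for the latter), as the leukocyte genes lie near the floor. Diet stays open as an explanation throughout, since each diet has 1 library.

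The first pattern is the excess of snoRNA and snRNA genes, and of several coding genes that hold them, in the HFD library. A general shift towards shorter RNA predicts larger ratios for shorter genes. Across 428 small RNA genes of up to 350 bases Spearman's rho of the log2 ratio on length was 0.20 (bootstrap interval 0.11 to 0.29). Genes are not independent replicates. The shortest 1197 coding genes had a median of -0.42 against -0.11 for all. Both were opposite to the prediction, but the coding part cannot separate length from GC content, which ratios of coding genes also followed (rho -0.27). Small RNA reads counted in their host genes may explain part of the excess at the 14 hosts that were over 2-fold higher and listed in both libraries. These hosts were picked for being higher. At 21.4% of them (3 of 14) the small RNAs inside gained at least as many reads as the host. At 5, Hspa8 and Rpl13 among them, the small RNAs are listed at 0 in both libraries and their reads cannot be seen. The 3 inside Rpl5 are listed and gained only 0.02 of its gain. In the first version of the test, all 214 hosts had a median of -0.11 (percentile 15.18 of random coding lists), the same as all coding genes. Of the hosts, 19 were over 2-fold higher and 26 lower. The share over 2-fold higher was 8.9%, against 8.0% of all coding genes, so hosts as a group showed no excess. Recovery of small RNA in library preparation was not tested.

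The second pattern is the deficit of pancreatic, endocrine, fibroblast and smooth muscle markers in the HFD library. A lower share of every other cell type in the HFD sort by about the same factor would lower all their markers alike. The lower quartile of the pit cell markers, 0.06, lay above the highest upper quartile of these 4 lists, -0.57, so pit cell markers were not lower with them. The 4 lists were picked for being low and the pit values had been seen, so this comparison cannot decide the question. A change in pit cells also stays open. Chief cells as the source of the pancreatic genes predict a pancreatic median within the range of the chief cell markers, whose lowest ratio was -1.93 for Pga5. The pancreatic median of -5.09, and that of the 3 genes listed in both libraries, -2.86, lay below it. This argues against chief cells for this list as a set, although Try4 at -1.71 lay inside the chief cell range. Pancreatic cells or RNA in the control library remain a candidate source, which a cell sort should have removed. A second list, none of whose 20 genes is in another list, had a median of -1.23 (percentile 0.28) with 13 of 15 measured genes lower. Only 7 were listed at 0 in the HFD library, and Cela1, at 83.6 against 92.9 RPKM, was nearly equal. The second median lay inside the chief cell range, between Pga5 and Bhlha15 (ratio 1.22). Chief cells therefore stay open as a source for the second list. Ctrb1 at 159 RPKM and Clps at 12989 RPKM in the control library, and 3 of 12 listed genes in the HFD library, leave open gastric expression of some of them.

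The third pattern is the higher interferon, parietal and fatty acid oxidation genes with lower cell cycle genes. Ratios of coding genes followed GC content (Spearman's rho across genes -0.27), with a median of 0.40 in the lowest of 20 GC bins and -0.62 in the highest, and length (rho 0.14). After this trend was taken out, interferon genes lay at percentile 100 and proliferation at 0.00, with medians of 0.84 and -1.17, which argues against GC content and length as the whole cause of these. Parietal markers lay at percentile 95.2 and fatty acid oxidation at 96.37, inside the random range as before the correction, so the test leaves the cause open for them. The diet and the cell make-up of the sort were not tested here as causes of this pattern.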
